A study of Mus musculus with 9 samples.

How the data were processed

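Total RNA of sorted lung cells was labelled with biotin and hybridised to whole-transcript oligonucleotide arrays, per the labels' protocols. The deposited values are log2 expression values made by the authors with RMA, using affy 1.36.1 in R 2.15.1, per the submitters' processing notes. RMA corrects background, quantile-normalises the arrays and summarises probes to a value per probe set on the log2 scale. Quantile normalisation sets the arrays to nearly the same distribution, so a change of all transcripts together could not be seen, and signal near the upper end of the scale compresses folds, as background does for dim genes. RMA values carry no detection call, so it is unknown which dim probe sets were above background. The genome build and the sort markers are not given in the sources used here, and scanner files were not used here, so scan date and array batch were not tested.

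Arrays were assigned to groups from their titles, which call them biological replicates, and the series text describes 3 separate groups of mice with 3 in each. The table holds 21225 probe sets, each named by a gene ID followed by a suffix. GEO's platform annotation gave 20239 of them 1 gene symbol, none several, and 986 none, and the gene IDs of all 20239 were found in the RefSeq gene table of assembly GRCm38.p6, used for names and neighbouring genes only. No coordinates are printed because the build of the probe sets is not given. No gene had more than 1 probe set.

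The test was chosen before the data were examined. All 9 arrays were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, with 6 residual degrees of freedom and no covariate, and contrasts were infected minus uninfected epithelial cells and infected epithelial minus infected non-epithelial cells. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 21225 probe sets, with a threshold of 0.05 and no filter on dim probe sets. Genes that differed from both other groups were called by an intersection-union test, taking the larger of the contrasts' p-values before adjustment. An exact rank or permutation test of 3 against 3 arrays cannot go below p = 0.1, which is why none is given per gene.

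The 36 gene lists of pathways and cell type markers, with 558 genes of which 510 were measured, were fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry, adjusted over the 36 lists. Lists among genes higher than in both other groups were tested with one-sided Fisher's exact tests against all named genes, and, added after seeing the data, against the named genes called on the same side between fractions. Some genes stand in more than 1 list, and Fisher's exact test takes genes as independent, which members of a list are not. Genes are named by a rule fixed in the same way, leaving out symbols of Gm and digits, those ending in Rik and those beginning with LOC, Mir, Snor, Olfr or n-R5s. It takes per contrast the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, the 15 genes with the largest smaller change among those higher than in both other groups, and the 10 likewise among those higher with infection and lower than in non-epithelial cells. It adds the 2 highest and 2 lowest members of each list, and Sectm1a, Sectm1b, Epcam, Ptprc, Cxcl5, Ccl20, Lcn2 and Sftpc in any case. Csf2 and Il34, outside this rule, were named after their values were seen.

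Calls were tested on simulated data with independent normal errors for 21225 genes, 200 of them changed. In the real data many more genes were called and list members were correlated, so the simulated shares need not carry over. For infection 61.19%, 86.57% and 98.48% of the genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 9 calls among unchanged genes. For the cell fractions the shares were 67.16%, 98.51% and 98.48% with 14 such calls, and for the intersection 55.22%, 89.55% and 100% with 0. The alternatives were only the groups compared in each fit, a filter on dim probe sets (above the 25th percentile of all values on at least 3 arrays), cyclic loess on top of the deposited values, a variance prior with trend and robust estimation, array weights, unnamed probe sets left out, the replicate number as a block, and leaving out each array in turn. A subtraction of non-epithelial RNA and the removal of infected epithelial replicates 1 and 3 together were added after seeing the data.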

Results

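Gene expression was measured in sorted lung cells of C57BL/6 mice, a common inbred laboratory strain, on 9 arrays. The arrays formed 3 groups of 3, each array from a separate mouse according to the labels. The groups were epithelial cells of uninfected mice, epithelial cells of mice 15 h after infection of the lung with pneumococcus, a bacterium that causes pneumonia, and non-epithelial cells of mice at the same 15 h. There was no group of non-epithelial cells from uninfected mice, so a change with infection could be tested in epithelial cells alone. Values were log2 expression per gene-level probe set, with medians of 6.82 to 6.92 per array over 21225 probe sets, and the number of arrays limits the precision. Pearson correlations across probe sets were 0.9939 to 0.9974 within groups, 0.9617 to 0.9735 between infected and uninfected epithelial arrays, and 0.8314 to 0.8457 between infected epithelial and infected non-epithelial arrays.

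The labels of the cell fractions were first set against Epcam, an epithelial adhesion molecule (gene ID 17075), and Ptprc, which encodes the leukocyte antigen CD45 (gene ID 19264). Epcam stood at 9.85 ± 0.01 in uninfected epithelial, 10.06 ± 0.11 in infected epithelial and 5.54 ± 0.23 in infected non-epithelial cells (log2, SD, n = 3 each, as for every mean ± SD). Ptprc stood at 6.21 ± 0.23, 6.69 ± 0.62 and 11.49 ± 0.07 in the same order. Neither gene passed the test for infection in epithelial cells, with log2 changes of 0.21 for Epcam and 0.48 for Ptprc and limma adjusted p of 0.193 and 0.2. Without infected epithelial replicate 2 Ptprc passed (log2 change 0.81, adjusted p = 0.00454, where the alternatives ran up to 0.585), and Epcam passed with the compared groups alone in the fit (adjusted p = 0.0452). Sftpc, the surfactant protein of alveolar type II cells, was at 12.84 ± 0.05 in infected epithelial cells and at 10.54 ± 0.22 in the non-epithelial fraction.

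**Figure D1:**
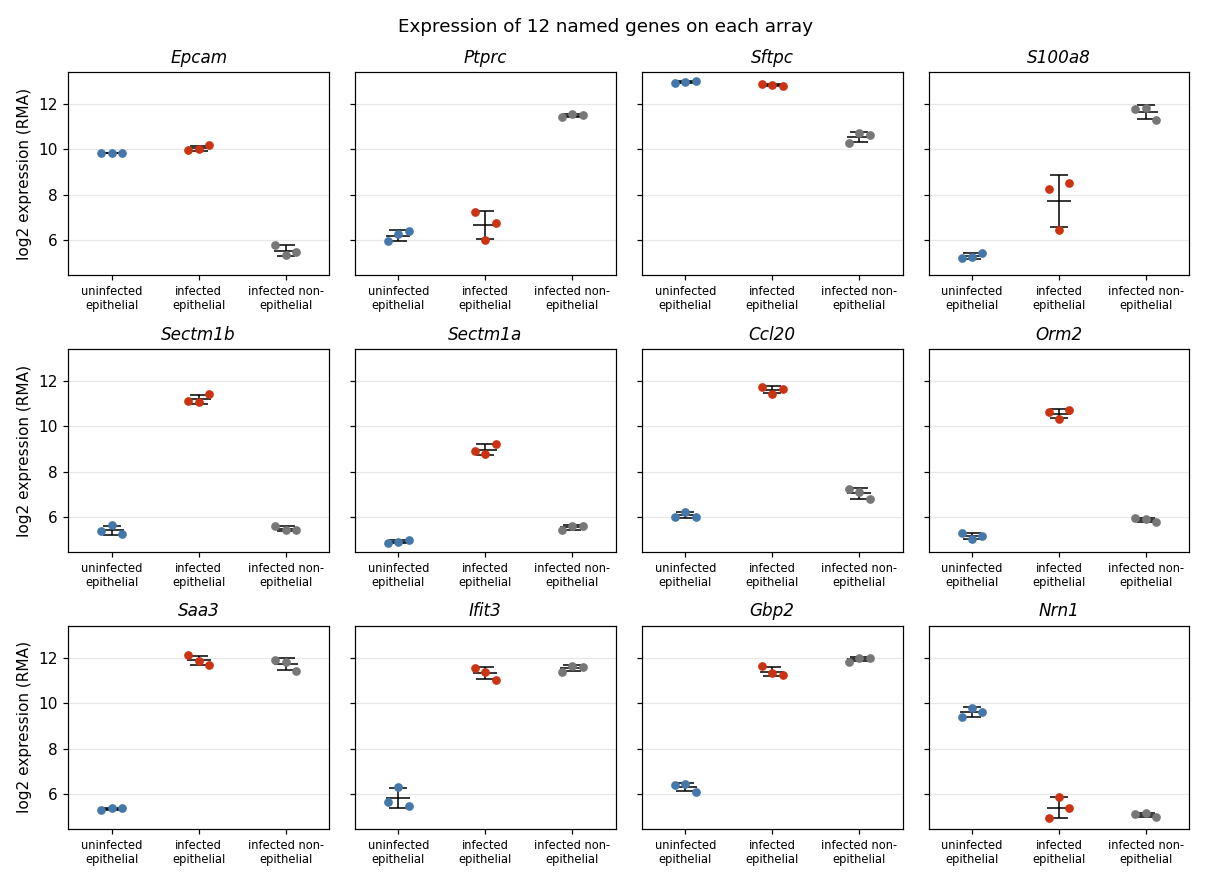
Log2 expression of 12 genes (y axis) in the 3 groups (x axis), with a point per array and bars for the mean and SD of 3 arrays. Sectm1b and Ccl20 stand higher on the 3 infected epithelial arrays than on the other 6, whereas Saa3, Ifit3 and Gbp2 are high in both infected fractions.

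The first comparison asked how the transcriptome of lung epithelial cells differed between infected and uninfected mice. Among named genes the largest rise was that of Saa3, an acute-phase serum amyloid (gene ID 20210), from 5.34 ± 0.04 to 11.88 ± 0.22, which is 93.2-fold (log2 change 6.54, SE 0.14, adjusted p = 5.2e-09). Orm1, another acute-phase protein, rose by 5.98 on the log2 scale, Sectm1b, of the secreted and transmembrane protein 1 family, by 5.77, the chemokine gene Ccl20 by 5.54 and the interferon-induced Ifit3 by 5.50. The largest fall was that of Nrn1, encoding neuritin (gene ID 68404), from 9.60 ± 0.21 to 5.40 ± 0.46, which is 18.4-fold (log2 change -4.21, SE 0.20, adjusted p = 3.5e-07). For each of these genes the 3 infected and 3 uninfected arrays did not overlap, which the naming rule required.

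Among the 12 largest rises, the log2 changes of the remaining genes ran from 5.08 for Gbp2 to 6.16 for BC023105. They included the acute-phase genes Orm2 (5.39) and Orm3 (5.28), the interferon-induced Ifit3b (5.11), and Iigp1 (5.24) and Gbp5 (5.12), which encode interferon-inducible GTPases. Orm1, Orm2 and Orm3, Sectm1a and Sectm1b, Ifit3 and Ifit3b, and the Gbp genes are families of related sequence, and signal shared between members was not excluded. Among the 12 largest falls were Bub1, a mitotic checkpoint kinase (log2 change -3.42), Lgi3 (-3.12), Acoxl (-3.09), Aox3, an aldehyde oxidase (-2.86), and the receptor tyrosine kinase gene Ros1 (-2.86). Bub1 and Acoxl lie next to each other in the gene annotation, and Bub1 stood apart from the other 18 measured cell cycle genes, whose median change was -0.024.

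All 21 measured type I interferon-stimulated genes rose, with a median log2 change of 3.13, among them Ifit3 and Ifit2 (5.05), and the smallest rise was that of Irf9 (1.49). The camera test gave an adjusted p of 1.7e-25, and adjusted p = 0.144 with an estimated correlation. Of 20 interferon-gamma-inducible GTPases and immunoproteasome genes, 19 rose (median 2.57), led by Iigp1, Gbp5 and Gbp2, and the change of Irf8, an interferon regulatory factor gene, was 0.29 and did not pass over all genes. Irf8 passed without infected epithelial replicate 2 (0.40) or non-epithelial replicate 3 (0.29), with adjusted p of 0.0314 and 0.0473. The adjusted p of this list was 6.66e-21, and adjusted p = 0.144 with an estimated correlation. Markers of neutrophils and of leukocytes at large were higher in the same arrays, as given below. MHC class II genes as a list did not pass (median -0.31, adjusted p = 0.324), though they did without infected epithelial replicate 2 (adjusted p = 0.0301). Of the 8 members H2-Aa alone was called, at -0.50, and its call ended without any 1 of the uninfected epithelial arrays, infected epithelial replicates 1 or 3 or non-epithelial replicate 1, with adjusted p of 0.0552 to 0.141, and with the replicate number as a block (adjusted p = 0.074).

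Of the 14 genes listed as neutrophil chemokines and growth factors, 12 rose, among them Ccl20 and Cxcl5 (4.22). The list is broader than its name, since members such as Ccl20 and Il34 are not specific to neutrophils. Cxcl15 fell by 0.31, a call that ended without infected epithelial replicate 3 (adjusted p = 0.0503, where the alternatives ran from 0.0026). The list had a median of 1.79 and an adjusted p of 1.03e-08, and its call held with an estimated correlation (adjusted p = 0.0166). So did that of the NF-kB feedback and target genes, of which 16 of 18 rose, including Tnip3 (4.25) and Tnfaip2 (3.49), while Traf1, encoding a TNF receptor adaptor, fell by 1.47 (list adjusted p = 1.08e-13, and adjusted p = 0.0166 with an estimated correlation). Monocyte and lymphocyte chemokines were higher in the infected epithelial sort in 13 of 16 cases, led by Cxcl10 (33.0-fold) and Ccl3 (31.9-fold), with adjusted p = 8.68e-11, and adjusted p = 0.0529 with an estimated correlation. Acute cytokines were higher in it in 9 of 14 cases, led by Il1a (3.72) and Il1rn, the interleukin 1 receptor antagonist gene (3.27), with adjusted p = 1.07e-05, and adjusted p = 0.166 with an estimated correlation. In the same arrays neutrophil and pan-leukocyte markers were higher by medians of 1.32 and 0.60. The differences from uninfected cells made a median of 4.27% of the non-epithelial level for these chemokines and 5.92% for the cytokines, where the median was 3.41% over the 13 neutrophil markers at least 16-fold higher in non-epithelial than in uninfected epithelial cells.

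Of 20 STAT3 and acute-phase genes, 15 rose, including Steap4, a metalloreductase gene (4.39), and Fgg, a fibrinogen chain gene (2.94), and Lifr fell by 1.06 (list adjusted p = 9.23e-10, and adjusted p = 0.162 with an estimated correlation). Complement genes rose in 7 of 14 cases, among them Cfb (4.20), with adjusted p = 2.98e-04, and adjusted p = 0.144 with an estimated correlation. Of 22 pattern recognition and cytokine receptors, 13 rose, among them Cd14 (2.86) and Tlr2 (2.33), and Tlr5 (-1.02) and Tlr4 (-0.46) fell (adjusted p = 5.31e-06, and adjusted p = 0.304 with an estimated correlation). Of 23 antimicrobial and mucosal defence genes, 9 rose and 3 fell (adjusted p = 6.34e-04, and adjusted p = 0.33 with an estimated correlation). That list held Sectm1a (4.05) and Sectm1b because published work on this series followed them up, so it is not independent evidence for them. Leukocyte markers were higher in these arrays too. S100a8 (2.42) and S100a9 (1.88) of the antimicrobial list are also neutrophil markers, Cd14 is also in the macrophage list, and Tlr2 stood lower than in non-epithelial cells (-2.95). Pigr, the receptor that carries immunoglobulin across epithelium, rose by 2.43 and Lcn2, an iron-sequestering defence protein, by 0.73, from an uninfected level of 12.10 ± 0.04.

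The unfolded protein response list rose in 12 of 17 cases, led by Sdf2l1 (1.67) and Manf (0.89), with adjusted p = 2.21e-06, and adjusted p = 0.304 with an estimated correlation. NRF2 and oxidative stress genes rose in 10 of 16 cases, led by the cystine transporter gene Slc7a11 (3.84) and Gpx2 (2.45), and Cat fell by 0.66 (adjusted p = 1.16e-05, and adjusted p = 0.304 with an estimated correlation). Fatty acid and cholesterol synthesis genes fell in 9 of 16 cases, among them Scd2 (-1.58) and Acaca (-1.50), and Elovl6, a fatty acid elongase gene, rose by 1.75 (list adjusted p = 0.00206, and adjusted p = 0.455 with an estimated correlation). Glycolysis and hypoxia genes rose in 7 of 17 cases, led by Egln3 (1.40), and fell in 3 (adjusted p = 0.0266, and adjusted p = 0.33 with an estimated correlation). The glycolysis and hypoxia list did not pass after cyclic loess (adjusted p = 0.119) or with dim probe sets left out (adjusted p = 0.0557), where the alternatives ran from 7.09e-04 to 0.33. Leukocyte markers were higher in these arrays too, and Slc7a11 (-2.78), Egln3 (-3.24) and Adm (-1.40), of the NRF2 and glycolysis lists, stood lower than in non-epithelial cells. Of the 17 glycolysis and hypoxia genes, 6 were higher with infection and lower than in non-epithelial cells (Fisher's exact adjusted p = 2.13e-04, and 0.0111 against named genes lower than in non-epithelial cells). Immediate early and heat shock genes (4 of 17 higher), cell cycle genes (2 of 19 lower), tight and adherens junctions (3 higher and 3 lower of 15) and ribosomal proteins (2 of 7 lower) did not pass as lists by camera, with adjusted p of 0.191, 0.846, 0.497 and 0.474. Junctions passed as higher and ribosomal proteins as lower by fry (adjusted p of 0.0321 and 0.0108), which tests whether genes move one way on balance, without comparing them with other genes. Immediate early and heat shock genes passed without uninfected epithelial replicate 2 (adjusted p = 0.0484).

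Alveolar type II markers fell in 6 of 15 cases, with a median of -0.24, led by Etv5, a transcription factor gene (-2.28), and Hc, encoding complement C5 (-1.07) (list adjusted p = 0.00433, and adjusted p = 0.438 with an estimated correlation). The changes of Sftpc (-0.13) and Chil1 (0.12) did not pass the test. In uninfected epithelial cells 14 of the 15 lay above 11.62, the top 1% of all values. Ciliated cell markers rose in 10 of 15 cases (median 0.43), among them Foxj1, the regulator of ciliogenesis (0.79), with adjusted p = 1.1e-04, and adjusted p = 0.33 with an estimated correlation. A change in the share of ciliated cells in the sort was not tested apart from a change within these cells. Mucins and secretory cell genes rose in 4 of 12 cases, led by Agr2 (2.79) and Muc4 (1.71), with adjusted p = 0.00571, and adjusted p = 0.455 with an estimated correlation. Alveolar type I markers (3 higher and 4 lower of 14, median -0.20 but mean 0.04), club cell markers (2 of 12 higher), basal cell markers (1 of 8 higher) and pan-epithelial markers (5 higher and 3 lower of 15) did not pass by camera, with adjusted p of 0.497, 0.687, 0.173 and 0.0728. By fry pan-epithelial markers passed as higher (adjusted p = 5.5e-04) and alveolar type I markers as lower (adjusted p = 0.0121). Without uninfected epithelial replicate 2 pan-epithelial and basal cell markers passed (adjusted p of 0.0371 and 0.0235), and basal cell markers passed without infected epithelial replicate 3 (adjusted p = 0.0129).

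Some markers of leukocytes were higher in the infected epithelial cells too. Neutrophil markers rose in 11 of 17 cases (median 1.32, adjusted p = 6.13e-06, and adjusted p = 0.381 with an estimated correlation). Pan-leukocyte markers rose in 9 of 14 cases (median 0.60, adjusted p = 7.82e-04, and adjusted p = 0.455 with an estimated correlation), and did not pass by fry (adjusted p = 0.0558). S100a8, a calgranulin abundant in neutrophils, read 8.24, 6.44 and 8.52 on infected epithelial replicates 1, 2 and 3, against 5.31 ± 0.13 in uninfected epithelial and 11.65 ± 0.29 in non-epithelial cells. Macrophage and monocyte markers rose in 5 of 16 cases, led by Mpeg1 (3.05) and Cd14, and Mrc1 fell by 0.73 (adjusted p = 0.0266, and adjusted p = 0.437 with an estimated correlation). That list did not pass without infected epithelial replicate 1 (adjusted p = 0.0945) or with dim probe sets left out (adjusted p = 0.0557), where the alternatives ran from 2.81e-04 to 0.437. Markers of T and NK cells (1 of 16 lower), B cells (1 of 10 lower) and endothelium (2 higher and 3 lower of 15) did not pass as lists, with adjusted p of 0.846, 0.168 and 0.846. Neither did markers of fibroblasts (2 higher and 2 lower of 14, median 0.09 but mean -0.07), smooth muscle and pericytes (1 of 10 higher, median -0.02 but mean 0.02), erythroid cells and platelets (1 of 8 higher) and mesothelium (2 of 8 higher), with adjusted p of 0.698, 0.842, 0.324 and 0.0611, though erythroid and platelet markers passed by fry (adjusted p = 0.0456). The medians of the T and NK cell and endothelial lists were 0.04 and 0.01, with fry giving the lower direction for both and for fibroblasts. Mesothelial markers passed without uninfected epithelial replicates 1 or 2 or infected epithelial replicate 3 (adjusted p = 0.0361, 0.00321 and 0.0269) or with the replicate number as a block (adjusted p = 0.0151).

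In all, 6581 probe sets (31%) passed the test for infection, 3067 higher and 3514 lower, and 1151 of them changed at least 2-fold, 652 higher and 499 lower. The balance turned after cyclic loess, with 3558 higher and 3035 lower, and the median change over all probe sets went from -0.0223 to 0.0194. The arrays of both groups did not overlap for 45.7% of probe sets, where chance gives 10%. Of the 36 lists, 18 were called higher and 2 lower by camera, 2 were called with an estimated correlation and 24 by fry. Of the 10 splits of the 6 epithelial arrays into 3 and 3, 4 gave at least 20 camera lists, the real one included. The highest count in another split was 23. Every other split keeps part of the infection difference between its sides, so these counts cannot tell whether the number of camera lists exceeds chance. Adjusted over the list alone, the counts of higher members became 14 for monocyte and lymphocyte chemokines, 16 for STAT3 and acute-phase genes, 20 for interferon-gamma-inducible genes, 10 for antimicrobial genes and 14 for receptors. They became 14 for the unfolded protein response, 11 for NRF2 genes, 8 for glycolysis genes and 10 for pan-leukocyte markers. The count of lower members became 8 for type II markers, 3 for receptors and 1 for neutrophil markers. For the remaining called lists they were the same. Of the lists not called, the count of higher members became 5 for junctions, 6 for pan-epithelial and 4 for endothelial markers and 0 for basal and smooth muscle markers. That of lower members became 1 for the cell cycle and 0 for MHC class II and B cell markers, and the others were the same. With infected epithelial replicates 1 and 3, the arrays of higher neutrophil marker level, left out together, a setting chosen after seeing the data, 3484 probe sets were called. It leaves 1 array in the group, whose spread is taken from the other groups by assumption.

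**Figure D2:**
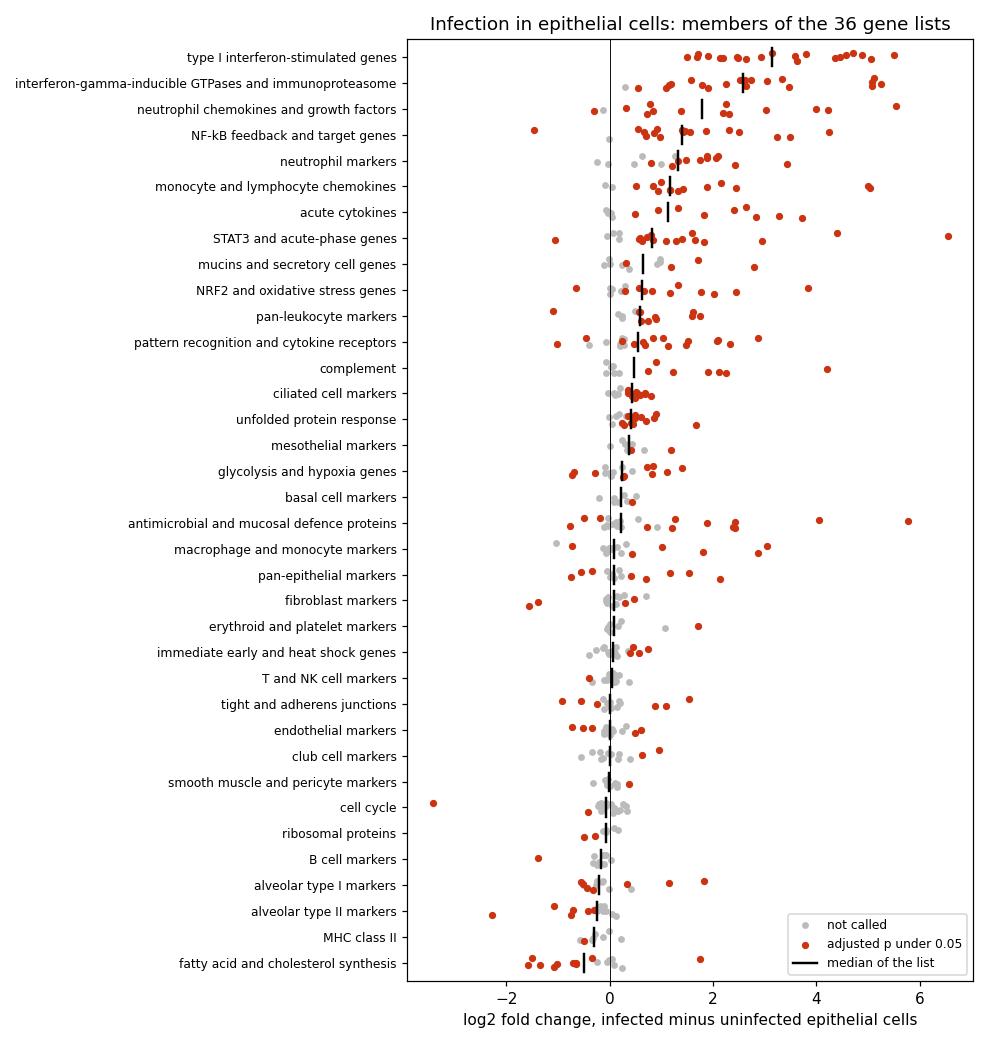
Log2 fold change between infected and uninfected epithelial cells (x axis) of the measured members of the 36 gene lists (y axis), from means of 3 arrays per group. A point is a gene, red where limma's adjusted p was under 0.05, and a black bar marks a list's median, highest at 3.13 for type I interferon-stimulated genes and lowest at -0.50 for fatty acid and cholesterol synthesis.

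The second comparison set epithelial against non-epithelial cells of infected mice. Genes of motile cilia were among those with the largest differences towards epithelial cells, with Cfap206 at 11.25 ± 0.12 against 5.26 ± 0.03, which is 63.8-fold (log2 difference 6.00, SE 0.09, adjusted p = 7.9e-11), and Rsph4a at a log2 difference of 5.94. Sectm1b (5.70), the water channel gene Aqp4 (5.56) and Lamp3, a type II cell marker (5.49), were also among the 12 largest. In the other direction stood leukocyte genes, among them the chemokine receptor gene Ccr2, at 4.26 ± 0.27 against 9.92 ± 0.20 (log2 difference -5.67, SE 0.14, adjusted p = 3e-10), the complement receptor gene C3ar1 (-5.70) and Cd86, a costimulatory molecule gene (-5.57). Each of these genes separated the 3 epithelial from the 3 non-epithelial arrays, which the naming rule required.

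All 15 pan-epithelial, all 15 alveolar type II and all 15 ciliated cell markers were higher in the epithelial fraction, with median log2 differences of 3.60, 2.91 and 4.08, and so were 11 of 12 club cell markers (2.27). All 14 pan-leukocyte, 16 T and NK cell, 10 B cell and 15 endothelial markers were lower (medians -4.43, -3.44, -2.79 and -1.53), as were 16 of 17 neutrophil and 14 of 16 macrophage and monocyte markers (medians -3.96 and -3.41). Ltf, encoding lactoferrin, was the neutrophil marker that was higher (2.62). In these 10 lists the camera adjusted p lay between 6.47e-11 and 1.04e-05. The pan-epithelial call held with an estimated correlation (adjusted p = 0.0277), as did that of tight and adherens junctions, of which 14 of 15 were higher and Cldn1 lower at -4.29 (adjusted p = 2.63e-08, and adjusted p = 0.0269 with an estimated correlation). The other 9 did not hold, with adjusted p of 0.108 to 0.282 with an estimated correlation.

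Of the immune lists, monocyte and lymphocyte chemokines were lower in epithelial cells for 15 of 16 genes (median -3.36), with Cx3cl1 higher (1.74). Acute cytokines were lower for 12 of 14 (median -2.96), with Il33 higher (2.69). NF-kB genes were lower for 16 of 18, complement for 12 of 14, receptors for 17 of 22, type I interferon-stimulated genes for 16 of 21 (median -0.69) and interferon-gamma-inducible genes for 14 of 20 (median -0.65). The camera adjusted p of these 7 lists ran from 4.59e-07 to 0.0137, and with an estimated correlation from 0.108 to 0.506. MHC class II genes were lower for 6 of 8 (adjusted p = 0.0466, and adjusted p = 0.469 with an estimated correlation). That call ended without infected epithelial replicates 1 or 3 or non-epithelial replicates 1 or 3 (adjusted p = 0.0597 to 0.0929), and with dim probe sets left out (adjusted p = 0.0501), where the alternatives ran from 0.00406.

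Antimicrobial genes were higher in epithelial cells for 15 of 23, among them Pigr (5.34), and lower for 5 (median 1.52, adjusted p = 4.73e-04, and adjusted p = 0.23 with an estimated correlation). Mucins and secretory cell genes were higher for 10 of 12 (median 3.49, adjusted p = 9.99e-05, and adjusted p = 0.239 with an estimated correlation). Fatty acid and cholesterol synthesis was higher for 14 of 16 (median 1.11, adjusted p = 8.32e-06, and adjusted p = 0.224 with an estimated correlation). Alveolar type I markers were higher for 8 and lower for 4 of 14 (adjusted p = 0.0061, and adjusted p = 0.108 with an estimated correlation). The unfolded protein response was higher for 11 and lower for 3 of 17 (adjusted p = 0.0195, and adjusted p = 0.462 with an estimated correlation). It did not pass after cyclic loess (adjusted p = 0.0544) or without dim probe sets (adjusted p = 0.0618), where the alternatives ran from 0.00422. Glycolysis and hypoxia (12 of 17 lower), cell cycle (16 of 19), fibroblast (12 of 14) and smooth muscle lists (6 of 10) were lower, with adjusted p of 6.98e-04, 0.00875, 0.00319 and 0.0111, and with estimated-correlation adjusted p of 0.129, 0.462, 0.119 and 0.255. The remaining 8 lists were not called by camera. They were neutrophil chemokines, STAT3 genes (median 0.02, with fry giving the lower direction), NRF2 genes, immediate early genes, ribosomal proteins, basal, erythroid and mesothelial markers, with adjusted p of 0.207, 0.833, 0.151, 0.344, 0.226, 0.0557, 0.151 and 0.0834. By fry 6 of the 8 passed. Neutrophil chemokines (6 higher and 6 lower of 14, median 0.01, adjusted p = 5.16e-08), NRF2 genes (8 higher and 5 lower of 16, adjusted p = 3.34e-05) and basal markers (4 of 8 higher, adjusted p = 0.029) passed as higher. Immediate early genes (3 higher and 6 lower of 17, adjusted p = 0.0128), ribosomal proteins (4 of 7 lower, adjusted p = 8.24e-05) and erythroid markers (5 of 8 lower, adjusted p = 3.92e-04) passed as lower. Basal cell markers passed without uninfected epithelial replicates 2 or 3 or infected epithelial replicate 3 (adjusted p = 0.0329, 0.0385 and 0.0113). Mesothelial markers passed without uninfected epithelial replicate 3 (adjusted p = 0.0162) or after cyclic loess (adjusted p = 0.048). With the replicate number as a block basal and mesothelial markers passed (adjusted p = 0.019 and 0.0226).

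Between the fractions 12249 probe sets (57.7%) passed the test, 5622 higher and 6627 lower in epithelial cells, and 4626 differed at least 2-fold. Groups did not overlap for 62.7% of probe sets, where chance gives 10%. Adjusted over the list alone, the counts were as above except for 18 lower receptors, 9 higher type I markers, 15 lower macrophage markers and 7 lower smooth muscle markers. Of the 36 lists, 10 were called higher and 18 lower by camera, 2 were called with an estimated correlation and 34 by fry.

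The 3 groups together allowed genes to be found that were higher in infected epithelial cells than both in uninfected epithelial and in infected non-epithelial cells. Sectm1b (gene ID 58210) led these, at 11.20 ± 0.20 against 5.42 ± 0.20 and 5.50 ± 0.10, which is 54.6-fold and 52.0-fold (log2 differences 5.77 and 5.70, SE 0.12 for both, adjusted p of the intersection-union test 2.68e-08). Sectm1a (gene ID 209588) stood at 8.97 ± 0.24 against 4.92 ± 0.06 and 5.55 ± 0.10, which is 16.5-fold and 10.8-fold (log2 differences 4.05 and 3.43, adjusted p = 1.97e-07). Ccl20 (gene ID 20297) stood at 11.61 ± 0.16 against 6.08 ± 0.13 and 7.05 ± 0.23 (log2 differences 5.54 and 4.56, adjusted p = 6.51e-08). The other leading genes included Orm2 (log2 differences 5.39 with infection and 4.67 over non-epithelial cells), Hpx, encoding the haem-binding hemopexin (3.51 and 4.18), and Hsd11b2, a glucocorticoid-inactivating enzyme gene (3.51 and 3.64). Fcer2a, encoding the low-affinity IgE receptor (4.64 and 3.35), and Slc26a4, encoding the anion exchanger pendrin (3.22 and 5.25), were among them.

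In total 1391 probe sets (6.55%) were higher than in both other groups, 210 of them at least 2-fold in both. Against the 20239 named genes, 6 lists were over-represented among the 1331 named ones by one-sided Fisher's exact tests. They included ciliated cell markers (10 of 15, adjusted p = 1.17e-07), the unfolded protein response (8 of 17, adjusted p = 8.77e-05) and STAT3 and acute-phase genes (8 of 20, adjusted p = 2.54e-04). Another was the list of neutrophil chemokines and growth factors (Cxcl5, Cxcl17, Ccl20, Csf2 and Il34 of 14, adjusted p = 0.0133), whose members are not all specific to neutrophils. Between fractions 6 of its members were higher and 6 lower in epithelial cells, with Cxcl3 (-2.8) and Csf1 (-1.67) lowest. The others were pan-epithelial markers (5 of 15, adjusted p = 0.0151) and antimicrobial genes (6 of 23, adjusted p = 0.0183, with Sectm1a and Sectm1b among the 6). Fisher's exact test takes genes as independent, so these p-values may be too small. The estimated inter-gene correlations of the 6 lists, in the order given, were 0.366, 0.403, 0.28, -0.0271, 0.0632 and 0.195. All named genes include many that are not higher in epithelial than in non-epithelial cells and could not have been in the group. Against the 5420 named genes that were, a background chosen after seeing the data, 4 lists passed, STAT3 and acute-phase genes (adjusted p = 4.69e-04), ciliated cell markers (0.0121), the unfolded protein response (0.0124) and neutrophil chemokines and growth factors (0.0382). Pan-epithelial markers (adjusted p = 0.698) and antimicrobial genes (0.631) did not. None of the 21 type I interferon-stimulated genes was in this group, where 1.38 were expected against all named genes. The one-sided test does not assess such an absence.

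A further 943 probe sets were higher with infection but lower than in non-epithelial cells, led by Ifi211 (4.27 and -3.93), Ifi204 (3.89 and -3.64) and Ifi205 (4.55 and -3.55), of a family of interferon-inducible DNA-binding proteins. Others were Il1a (3.72 and -3.49) and Clec4e, encoding a C-type lectin of myeloid cells (3.42 and -3.92). This group held 15 of the 21 type I interferon-stimulated genes (Fisher's exact adjusted p = 6.36e-15), 13 of 18 NF-kB genes (2.77e-13), 12 of 16 monocyte and lymphocyte chemokines (9.4e-13) and 10 of 17 neutrophil markers (2.81e-09). Against the 6317 named genes lower than in non-epithelial cells these adjusted p were 8.14e-11, 5.55e-08, 2.16e-07 and 7.79e-05. They may be too small, because Fisher's exact test takes genes as independent. The estimated inter-gene correlations of the same lists were 0.697, 0.0544, 0.115 and 0.614. The opposite combination held 1371 probe sets, among them Lgi3 (-3.12 and 3.34), and 842 were lower than in both other groups.

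Both contrasts share the infected epithelial arrays. Across probe sets, which are not independent, their fold changes correlated at r = -0.0314 (rho = 0.0147), where 100 simulations without any effect gave a mean r of 0.499. The simulated fold changes varied by noise alone, while many probe sets differed in the data, so these values of r cannot be compared directly. The covariance was -0.0209 against 0.00727 simulated, a difference of -0.0282. The 3 arrays are too few to split so that each part keeps at least 2. With infected epithelial replicates 1 and 3 left out together, 628 probe sets were higher than in both other groups. After subtraction of non-epithelial RNA at each array's median neutrophil marker share, 598 were higher with infection and lower than in non-epithelial cells. That share was applied to all non-epithelial RNA, although markers of other non-epithelial cells had lower median shares. Both settings were chosen after seeing the data.

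**Figure D3:**
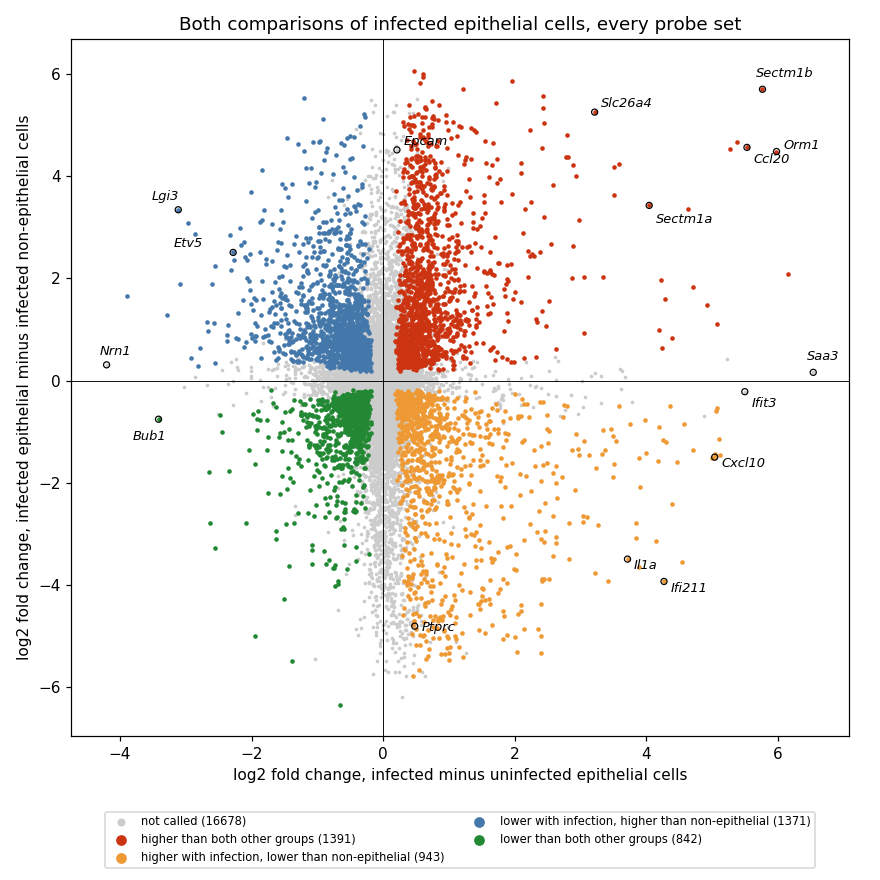
Log2 fold change between infected and uninfected epithelial cells (x axis) against that between infected epithelial and infected non-epithelial cells (y axis), from means of 3 arrays per group, with a point per probe set. Colours mark the 1391, 943, 1371 and 842 probe sets called in both comparisons, grey the others, and circled genes are named. Sectm1b lies at 5.77 and 5.70.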

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

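The alternatives were planned except the background of named genes higher in epithelial cells, the subtraction of non-epithelial RNA and the removal of infected epithelial replicates 1 and 3 together, which were chosen after seeing the data. No called list or named gene reversed under the alternatives in which it was run, and a count has no direction to reverse. Across the alternatives 156 values of named genes and 56 of lists lost a call while 111 and 27 gained one. Camera was not rerun with the compared groups alone, a trended and robust prior, array weights or unnamed probe sets left out. Nor was it rerun for the subtraction or the removal. Probe set calls for infection numbered 6581 and ran from 5180 to 6907 with 1 array left out, those between fractions numbered 12249 and ran from 11210 to 11854, and those higher than in both other groups numbered 1391 and ran from 1071 to 1403. Array weights gave the highest count for infection, 8286. With infected epithelial replicates 1 and 3 left out, 3484 were called for infection, of which 3400 were among the 6581, and 628 were higher than in both other groups, where 1 array is left in the group and is assumed to vary like the other groups. After the subtraction 598 rather than 943 were higher with infection and lower than in non-epithelial cells, 2448 rather than 3067 higher with infection, and 1272 rather than 1391 higher than in both. The neutrophil marker share was subtracted for all non-epithelial RNA. Of markers at least 16-fold higher in non-epithelial than in uninfected epithelial cells, median shares were 3.41% for neutrophils, 0.317% for T and NK cells and 0.43% for macrophages and monocytes. Too much may therefore have been taken from genes of cells other than neutrophils. With an estimated correlation 2 rather than 20 lists were called for infection and 2 rather than 28 between fractions, and the cause was not tested. By fry 24 and 34 lists were called. After cyclic loess 3558 probe sets were higher and 3035 lower with infection, rather than 3067 and 3514, so which side was larger depended on the scaling. Over-represented lists numbered 4 rather than 6 against named genes higher in epithelial cells and ran from 5 to 7 with 1 array left out, and called lists from 19 to 24 and from 27 to 30. Replicate numbers did not pair the arrays. Same-numbered arrays of different groups correlated at -0.193 to 0.048 in their deviations from group means, and 0 of 9 arrays correlated best with their own number. With the replicate number as a block, 6109 probe sets were called for infection, 11686 between fractions and 1300 higher than in both, with 21, 30 and 6 lists. The calls of Fbln1 and Col17a1 for infection each ended without any 1 of 7 of the 9 arrays, with adjusted p up to 0.145 and 0.168. Signal over background is unknown for these values, and the dim filter, which removed 4644 probe sets, left 6628 calls for infection.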

Other observations

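The tests of chance splits were planned. All other tests in this part were chosen after the results were seen, so what they leave open is a hypothesis.

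Bub1 stood apart from the other cell cycle genes. Fewer dividing cells would have lowered those genes too, but the median of the other 18 was -0.024 (interquartile range 0.302). This argues against fewer dividing cells only as far as those genes were above background, which is unknown. Acoxl, the neighbouring gene, fell by a like amount (Bub1 minus Acoxl -0.325, SE 0.412), so signal from transcripts of the neighbour may account for it, though a change of both genes with infection was not tested apart and stays open. Of 66 genes that fell at least 4-fold, 9 had a neighbour that fell at least 2-fold, and without Bub1 and Acoxl, which prompted this count, 7 of 64 did, where 1000 shuffles of the gene order gave a median of 3 and a highest count of 10 (permutation p = 0.037). The shuffles ask only whether neighbours fell together, and cannot tell shared signal from neighbours that change alike.

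Neutrophil markers were higher in infected epithelial cells, and the 13 of 17 at least 16-fold higher in non-epithelial than in uninfected epithelial cells (5 of the 17 stand in other lists) made a median share of the non-epithelial level of 4.81%, 1.12% and 3.75% on infected epithelial replicates 1, 2 and 3. Neutrophil RNA in the sort, whose markers the labels do not give, cannot be told apart from a weaker response of replicate 2 or from a rise of these genes in epithelial cells, because on replicate 2 the markers differed from the mean of the others by a median of -1.09 on the log2 scale and the 15 genes highest in infected epithelium also lay lower (median -0.33), with overlapping ranges. The rise of the type I interferon-stimulated genes made a median share of 50.4%, that of the interferon-gamma-inducible genes 51% and that of the NF-kB genes 30.5%, with lower quartiles of 35.4%, 36% and 15%. Over all measured members no marker list of neutrophils, pan-leukocyte, T and NK, B, macrophage, endothelial or fibroblast cells had an upper quartile above 6.88%, which argues against RNA of these cells as the whole cause, although 11 single markers stood higher, Plet1 (102%), Cd14 (70.4%), Mpeg1 (39.2%) and Cd68 (24.9%) of the 16 macrophage markers (median 0.19%), Ltf (326%), Mxd1 (10.7%) and Retnlg (7.66%) of neutrophils, Dcn (14.6%), Col6a3 (13.1%) and Fbln1 (10.5%) of fibroblasts, and Rac2 (7.79%). Monocyte and lymphocyte chemokines, at a median of 4.27%, may come in part from such RNA, although Cxcl10 stood at 35.6% and Ccl3 at 34.5%, and for acute cytokines, at 5.92%, the sources cannot be told apart because the list's range spans the marker shares.

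Type II cell markers fell unevenly. Fewer type II cells in the infected sort would lower them alike, and Chil1 (0.12) and Hc (-1.07) differed by 1.186 (SE 0.17), but they were picked as the most different of 30 pairs of like uninfected level and both lay near the top of the scale, so this cannot be told apart from compression there. Compression stays open too, because the correlation of level and change over the 15 markers, which are not independent, was rho = 0.45 (Pearson 0.62, permutation p = 0.0943). A change in type II cell transcription with infection stays open as well, and was not tested apart from these.

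The count higher than in both other groups was 1391 for the real groups and at most 166 in the other drawn splits of the 9 arrays, and 1 of 100 splits reached it, the real one. The count of over-represented lists was 6 against at most 1, again reached by 1 of 100. Such splits can mix epithelial with non-epithelial arrays, which widens the spread within groups and lowers the counts. They therefore do not exclude chance for the infection part of the condition. For each pair of groups there are 10 splits, too few for a share under 0.05. Infection gave 6581 probe sets against at most 1 in the other splits, and the fractions gave 12249 against at most 0, each reached by 1 of 10. Each other split holds arrays of both groups on each side, which widens the spread and keeps only part of the difference. Low probe set counts there follow from the design and do not measure chance. Lists numbered 20 for infection against at most 23 in the other splits (4 of 10 reached 20). Between fractions lists numbered 28 against at most 23 (1 of 10). Camera compares list members with other genes, so the part of the difference that such splits keep can still give calls. The number of lists therefore cannot be set against chance in this way.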
